A study of Mus musculus with 12 samples.

How the data were processed

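Total RNA of the hippocampus of 3-month-old mice was sequenced from 12 libraries, 3 for each of 4 groups: control and Atrx conditional knockout (cKO) females and males. Per the labels, RNA was isolated with a miRVANA kit, and libraries were prepared after removal of ribosomal RNA with a ScriptSeq Complete Gold kit. Per the submitters' processing notes, reads were aligned with HISAT2 2.0.4 to GRCm38.p6 and quantified with StringTie. The trimming, the use of strand, the annotation release and which exons are deleted were not given in the sources used here. The design text of the series speaks of 3 pairs of control and cKO mice of either sex and of 12 samples, which reads as 1 mouse per library. Neither it nor the labels, which call the sample type hippocampal cells, state this for each library or say which libraries form a pair. All p-values therefore measure the spread between these libraries without pairing, and stand for mice only if each library is 1 mouse.

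The deposited tables give, for each library, the FPKM (fragments mapped, per unit of transcript length and of library size) of 137862 annotated transcripts. The same deposited tables give the coverage, the mean number of reads over each base of a transcript. Within each table, FPKM was a constant multiple of coverage, which was checked on the values. Transcript FPKM was summed to 54532 genes, of which 54495 matched a gene of the GENCODE M21 annotation. The tables hold no read counts. Mapped bases per library were recovered from the ratio of FPKM to coverage, and reads were estimated from them at a read length of 76 bases, itself read off the coverage of short transcripts. Depth ran from 1.16 to 8.64 Gb. Coordinates are 1-based and on GRCm38.p6. Because the use of strand is unknown, values of overlapping genes, paralogs and short RNAs inside host genes are uncertain.

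The following choices were made before the data were examined. FPKM was scaled by median-of-ratios factors over genes above 0 in all libraries, and genes with an FPKM of at least 0.5 in at least 3 libraries were kept. Values were analysed as log2(scaled FPKM + 0.5), so a fold of a low gene is smaller on this scale than the ratio of its FPKM values. limma (trend and robust) fitted the means of the 4 groups in 1 model over all 12 libraries. The comparisons were cKO against control in females, the same in males, the difference between these effects (male minus female), their mean, and control males against control females. Tests were two-sided, with Benjamini-Hochberg adjustment over genes within a comparison and a threshold of 0.05. Atrx was tested with exact two-sided permutation tests, whose smallest possible p is 0.1 within a sex and 0.005 with labels permuted within both sexes.

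A set of 27 gene lists was also fixed in advance. Lists on the gene and its reported biology were reported ATRX targets, ATRX partners and heterochromatin proteins, reported miR-137 targets, p53 and DNA damage genes, interferon response genes and imprinted genes. Neuronal lists were presynaptic release, postsynaptic glutamate signalling, GABA receptors, interneuron markers, immediate early genes, CA1 pyramidal, CA2 and CA3 pyramidal, dentate granule and immature neuron markers. Lists of other cells were oligodendrocyte, oligodendrocyte precursor, astrocyte, microglia, and endothelial and mural markers. Lists on dissection and library composition were choroid plexus, thalamus and habenula, striatum, blood, mitochondrially encoded genes, short structural RNAs and a sex chromosome check. Each list was tested with camera at a preset correlation of 0.01, and again with an estimated correlation, with adjustment over the lists of a comparison. The median of a list is given relative to the median of all genes tested. Members were counted over all genes and adjusted over the list alone.

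Genes were named by a rule fixed in advance. Atrx, Mir137, Xist, Ddx3y, Eif2s3y, Kdm5d and Uty were always reported. In each comparison, the 12 genes of smallest p in each direction were taken among those past the threshold with a mean FPKM of at least 1 in the higher group. Where fewer than 20 passed, the list was filled to 20 with genes that had not passed. At most 3 predicted genes were named per direction, and up to 4 members of each list were named. Gm10800 and Ttr were named after their values were seen.

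Coverage of genes for olfactory and vomeronasal receptors differed widely between libraries, so a background subtraction was added after seeing the data. For each gene, bases assigned to it were divided by the length of the union of its exons, and the median over 1461 receptor genes of the same library was subtracted, with values below 0 set to 0. Libraries were then scaled over protein-coding genes with a mean of at least 5 on this FPKM scale, and genes with a mean of at least 1 and a value of at least 1 in 3 libraries were kept. The model, tests, lists and naming rule were unchanged. This left 14770 genes, against 43399 in the analysis planned in advance. Without cKO females 2 and 3, the libraries of highest background, the subtracted data were tested again, which leaves 1 cKO female and takes its spread from the other groups.

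The pipeline was tested on simulated libraries in which 200 genes were changed in cKO females. With no background, the planned analysis recovered 56% of genes changed 2-fold and 100% of those changed 4-fold, with 24 false calls. With the measured background added, it recovered 13% and 49%, with 192 false calls in females and 75 in males. With the background subtracted, it recovered 37% and 99%, with 23 false calls in females and 0 in males. The simulation added 1 background level per library to every gene, whereas the measured background varied between genes. In cKO female 3 its quartiles over the receptor genes were 1.50 and 2.91. The rates after subtraction may therefore be too favourable for the real data.

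Other settings fixed in advance were FPKM as deposited, quantile normalization, pseudocounts of 0.1 and 1, no filter, a filter at an FPKM of 5, both forms of a replicate block, no robust option, library quality weights, voom on estimated reads, the libraries of a comparison alone, transcripts in place of genes, and leaving out each library in turn. Settings added after seeing the data were the background subtraction, the fits without 2 libraries, scaling over expressed protein-coding genes, and log2 background as a covariate. Libraries with the same number correlated at −0.525 to 0.585 across genes, before subtraction and after removal of group means, with genes not independent replicates, so the numbers were not used to pair them. Other splits of the libraries into groups of the same sizes were fitted, all 10 within a sex and 100 drawn at random over both sexes. Count models were not used, because the tables hold no counts. Calculations used R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.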

Results

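Total RNA of the hippocampus was measured in 12 libraries from 3-month-old mice: 3 control females, 3 Atrx-cKO females, 3 control males and 3 Atrx-cKO males. ATRX is a chromatin remodeller of the SWI/SNF family that deposits histone H3.3 at repetitive DNA. The title of the series places the deletion in neurons and names a miR-137 change that differs between the sexes. Mapped sequence was 6.79, 7.90 and 3.60 Gb in control females 1 to 3, and 4.26, 1.16 and 2.86 Gb in cKO females 1 to 3. In males it was 7.12, 8.19 and 7.99 Gb in controls and 8.49, 3.66 and 8.64 Gb in cKO. Group means were 6.10 ± 2.23 Gb in control females, 2.76 ± 1.55 Gb in cKO females, 7.77 ± 0.566 Gb in control males and 6.93 ± 2.83 Gb in cKO males (SD, n = 3 each).

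Genes for olfactory and vomeronasal receptors, which hippocampal cells do not use, were covered to very different degrees. Their median coverage on the FPKM scale, called background here, was 0.180, 0.0863 and 0.600 in the control females and 0.304, 1.97 and 2.25 in the cKO females. It was 0.0274, 0.0128 and 0.00664 in the control males and 0.0205, 0.286 and 0.0178 in the cKO males. The number of genes at an FPKM of 0.5 or more ran with it, from 17146 in control male 3 to 49483 in cKO female 3. Values are therefore given on the scale fixed in advance and after subtraction of this background, a step added after seeing the data.

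**Figure D1:**
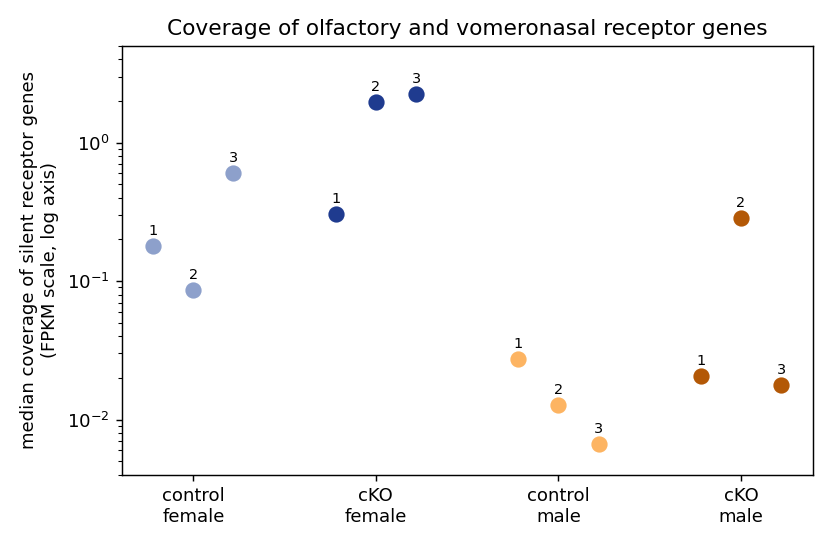
Median coverage of 1461 olfactory and vomeronasal receptor genes (FPKM scale, log axis) in each library, by group, with 1 point per library marked by its replicate number. cKO females 2 and 3 lie at 1.97 and 2.25, and the control males lie between 0.00664 and 0.0274.

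The sex labels matched the genes of the sex chromosomes in all 12 libraries. Xist, the RNA of the inactive X chromosome, had 17.6 ± 6.10 FPKM in control females and 12.8 ± 5.24 in cKO females, and at most 0.233 in any male (SD, n = 3). The Y-linked genes were found in males. Eif2s3y, a translation initiation factor, had 29.5 ± 3.62 FPKM in control males and 35.2 ± 2.45 in cKO males and was listed at 0 in every female. Ddx3y, an RNA helicase, had 30.5 ± 5.19 and 27.8 ± 1.19 FPKM. The histone demethylases Kdm5d and Uty had 6.28 ± 1.18 and 14.1 ± 4.16 FPKM in control males, 7.92 ± 1.10 and 12.9 ± 1.48 in cKO males, and at most 0.365 in any female.

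Atrx itself (ENSMUSG00000031229, minus strand of chromosome X, 105797615 to 105929403) was lower in every cKO library than in every control library of its sex. The controls had 55.6, 58.8 and 63.6 FPKM in females and 46.9, 40.2 and 42.1 in males, and the cKO libraries had 31.0, 36.1 and 38.2 in females and 34.2, 32.3 and 36.5 in males. The means were 59.3 ± 4.03 against 35.1 ± 3.71 in females and 43.0 ± 3.44 against 34.3 ± 2.09 in males (SD, n = 3). The log2 change was −0.75 and −0.32 on deposited FPKM, −1.47 and −0.57 on the scale fixed in advance, and −0.87 and −0.47 after background subtraction, for females and males. Exact two-sided permutation tests gave p = 0.1 within each sex and p = 0.005 over both, the smallest values they allow. The full-length transcript ENSMUST00000113573, with 35 exons and 43.5% of control Atrx FPKM, went from 23.8 ± 2.87 to 9.07 ± 1.70 FPKM in females and from 20.8 ± 0.688 to 13.3 ± 1.41 in males (n = 3; exact permutation p = 0.005 over both sexes). A transcript of 2 exons, ENSMUST00000200471, had log2 changes of 0.28 and 0.23 on deposited FPKM (exact permutation p = 0.005 over both sexes). It went from 1.64 to 2.10 FPKM in females and from 1.15 to 1.45 in males. The mean background went from 0.289 to 1.51 in the same females and from 0.0156 to 0.108 in the males, so the female rise cannot be told apart from background. Neither transcript p was adjusted over the 27 Atrx transcripts.

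**Figure D2:**
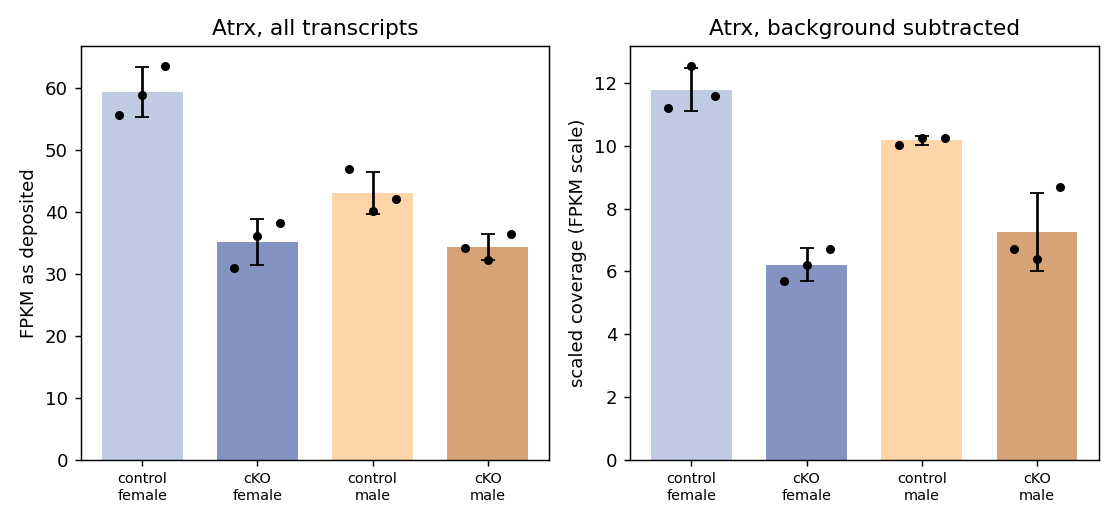
Atrx in each group as deposited FPKM (left) and as scaled coverage after background subtraction (right, FPKM scale), with bars for means, error bars for SD and 1 point per library (n = 3). On deposited FPKM the control females average 59.3 and the cKO females 35.1.

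The miR-137 precursor gene Mir137 (ENSMUSG00000065569, chromosome 3, 118433857 to 118433929) was close to the limit of detection. Its FPKM was 0.0409 ± 0.0176 in control females, 0.168 ± 0.236 in cKO females, 0.0525 ± 0.0255 in control males and 0.103 ± 0.117 in cKO males (SD, n = 3). After subtraction it was 0 in both female groups, and 0.0333 ± 0.0129 in control and 0.0677 ± 0.11 in cKO males. The highest values before subtraction, 0.440 in cKO female 2, where the background was 1.97, and 0.238 in cKO male 1, stood beside 0.00835 and 0.0272 in other libraries of the same groups. The gene did not pass the expression filter and was not tested, so a change in either sex could not be assessed. The entry is the precursor, and mature microRNAs were not measured. No gene was listed under the symbol Mir137hg, and a host gene of Mir137 under another name was not looked for.

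The comparison of cKO with control females asked which hippocampal genes respond to loss of Atrx in females. After background subtraction, 4 genes rose and 7 fell among 14770 tested. The same processing gave 23 false calls in females in the simulated libraries, where 200 genes were changed. Of 10 splits of the female libraries, 2 called at least 11 genes, the real one included. Single genes in this list may therefore be false calls. Mtfp1, a protein of the inner mitochondrial membrane that promotes mitochondrial fission, fell from 24.3 ± 0.27 to 14.2 ± 1.09 FPKM (SD, n = 3; log2 −0.69, SE 0.055, adjusted p = 0.0017). Fam155a, an auxiliary subunit of the sodium leak channel NALCN, fell from 33.5 ± 1.73 to 20.7 ± 0.374 FPKM (log2 −0.71, adjusted p = 0.0317). Sez6l, a neuronal membrane protein of the SEZ6 family, fell from 18.9 ± 1.35 to 7.43 ± 1.17 FPKM (log2 −1.24, adjusted p = 0.0327). Atrx fell by 0.87 (adjusted p = 0.0201). In each of these the 3 cKO libraries lay below the 3 controls, as deposited and after subtraction.

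Among the other genes that fell in cKO females were Cttnbp2nl, named for its likeness to a cortactin-binding protein (log2 −2.14, adjusted p = 0.0181), the histone H2B gene Hist3h2ba (−1.94, 0.0279) and the small nucleolar RNA Snora73b (−3.09, 0.0327). The 3 cKO libraries lay below the 3 controls in each after subtraction, where these folds rest on cKO values at or near 0: 0.33, 0 and 0 for Cttnbp2nl, 0.508, 0 and 0.091 for Hist3h2ba, and 0 in all 3 for Snora73b. Setting values below 0 to 0 also removes spread between such libraries, so the adjusted p-values of these 3 genes may be too small. As deposited, Cttnbp2nl had 5.32, 4.23 and 4.70 FPKM in controls and 2.53, 4.03 and 3.78 in cKO females, and Snora73b had 3.52, 10.5 and 2.55 against 0, 0.431 and 0.42. Hist3h2ba overlapped as deposited, with 2.88, 2.21 and 2.66 against 0.861, 1.64 and 2.31. Snhg8, a host gene of a small nucleolar RNA, rose (log2 0.70, adjusted p = 0.0176), as did the ubiquitin ligase Rnf19b (0.59, 0.0302), the pseudogene Gm37116 (1.85, 0.0176) and the small nuclear RNA Gm26127 (2.72, 0.0201), each higher in 3 of 3 libraries. Deposited FPKM of Snhg8 was 39.96 ± 1.78 in controls and 46.9 ± 14.2 in cKO females with overlapping libraries, and that of Rnf19b was 15.5 and 15.6. On the preset scale, which differs from the subtracted data in scaling and filter as well, both turned direction, with log2 −0.53 for Snhg8 and −0.72 for Rnf19b.

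On the scale fixed in advance, limma called 0 of 43399 genes in females, with 18176 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0701. voom on estimated reads called 1 gene. Genes lay apart by their mean coverage after subtraction. The median log2 change was 0.52 for genes under 0.1 and −1.13 for genes over 20, around a median of 0.34 for all genes. On deposited FPKM that median for all genes was 0.89, and 9846 genes were called higher and 606 lower. Genes under 0.1 could pass the filter of 0.5 FPKM in 3 libraries through cKO females 2 and 3 and control female 3, whose background exceeded 0.5. The filter itself thus favours a rise of these genes in cKO females. Named genes that did not pass included Bsn, a scaffold of the presynaptic active zone (log2 −1.45, adjusted p = 0.0876, 11.3 ± 2.74 against 6.10 ± 0.843 FPKM), Sez6l (−1.95, 0.0717), Snora73b (−2.93, 0.0717), the protocadherin Pcdhgb1 (−1.64) and the thymidylate synthase Tyms (1.07). Gm21980 (log2 3.51, adjusted p = 0.0701) was listed at 0 in all 3 controls.

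The count of 11 genes in females after subtraction depended on single libraries. It was 1 without control female 2, cKO female 2 or cKO male 1, 2 to 7 without any 1 of the control males, control females 1 and 3 or cKO male 3, 9 without cKO female 3 or cKO male 2, and 5556 without cKO female 1. Without both cKO females 2 and 3 it was 16, and Mtfp1, Cttnbp2nl and Hist3h2ba were in both lists. That fit leaves 1 library, cKO female 1, in the cKO female group, whose spread is taken from the other groups. Mtfp1 passed in all 12 fits that left out a library (adjusted p from 9.46e-05 to 0.0232), Snhg8 and Gm37116 passed in 8, and the other 8 genes passed in 1 to 4.

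**Figure D3:**
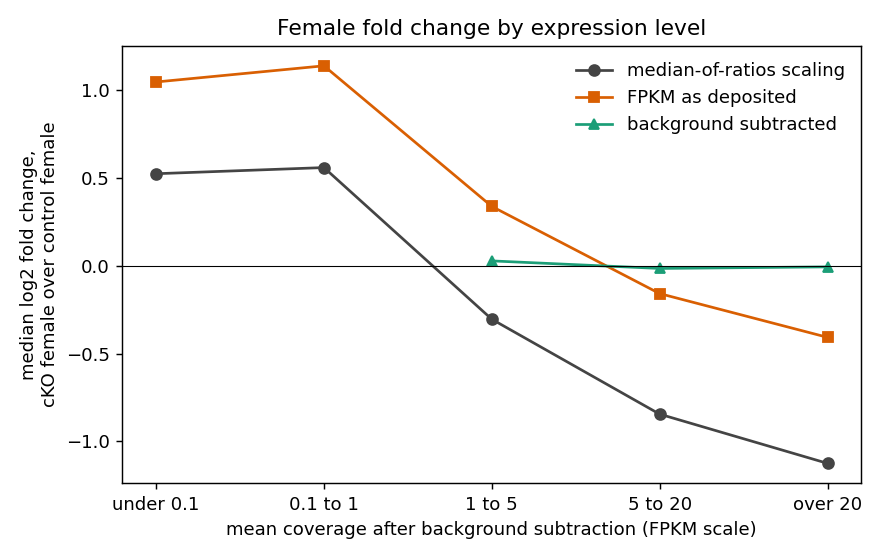
Median log2 change of cKO against control females (vertical axis) for genes grouped by mean coverage after background subtraction (horizontal axis, FPKM scale), with 1 line for each way of scaling. On the scale fixed in advance the medians run from 0.52 under 0.1 FPKM to −1.13 over 20, and after subtraction they lie between −0.02 and 0.03.

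The comparison of cKO with control males asked the same of males. Mtfp1 fell from 24.1 ± 0.891 to 15.5 ± 0.843 FPKM (SD, n = 3; log2 −0.64, SE 0.055, adjusted p = 0.00358) and was the 1 gene that passed after background subtraction. Fam155a had 24.9 ± 0.969 FPKM in controls and 15.5 ± 2.60 in cKO males (log2 −0.76, adjusted p = 0.081), and Snhg8 had 77.4 ± 1.32 and 104.5 ± 8.33 (0.44, 0.749). Atrx had a log2 change of −0.47 (adjusted p = 1). In each of these 4 genes the cKO libraries lay on 1 side of the controls in 3 of 3 libraries, after subtraction and on deposited FPKM.

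Other named genes in males did not pass. Pla2g2f, a secreted phospholipase, had 0.745 ± 0.142 FPKM in controls and 3.92 ± 0.28 in cKO males (n = 3; log2 1.79 after subtraction, adjusted p = 1). Tex13c2, an X-linked gene of a testis-expressed family, had 0.440 ± 0.0652 and 2.18 ± 0.19 FPKM (log2 1.47 before subtraction, adjusted p = 0.336). On deposited FPKM both genes were also higher in every cKO female than in every control female. Pla2g2f had 0.647, 1.08 and 0.801 in controls against 3.46, 2.27 and 2.71, and Tex13c2 had 0.830, 0.949 and 0.978 against 1.87, 3.81 and 2.35. After subtraction the female libraries of both overlapped. The centrosomal protein gene Cep112 had 17.0 ± 1.48 and 6.498 ± 0.533 FPKM (−1.57 before subtraction, 0.824). Csf2ra, a subunit of the receptor for a myeloid growth factor and a reported ATRX target, had 1.86 ± 0.455 and 0.894 ± 0.206 FPKM in males and 1.94 ± 0.181 and 1.17 ± 0.185 in females. It was lower in 3 of 3 cKO libraries of each sex. Before subtraction it passed in both when adjusted over the list alone (adjusted p = 0.00596 in females and 0.00449 in males), but not over all genes (0.0876 and 0.91). In cKO females 2 and 3 its 1.33 and 0.967 FPKM lay below the background of 1.97 and 2.25, and it was 0 in both after subtraction. It was not tested after subtraction.

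On the scale fixed in advance, limma called 0 genes in males, with 945 at an unadjusted p under 0.05, and voom called 0. The smallest adjusted p was 0.336, and the median of all genes was 0.11. After subtraction, Mtfp1 passed in all 12 fits that left out a library (adjusted p from 0.00652 to 0.0419), in which 1 or 2 genes were called. It did not pass without the subtraction (0.91), on deposited FPKM (0.991) or with quantile normalization (1).

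The mean of the female and male effects asked which genes responded to loss of Atrx on average over the sexes, which does not require a response in each. Of the genes called here, Mtfp1 alone also passed in males. After subtraction 2 genes rose and 3 fell. Mtfp1 fell by 0.66 on the log2 scale (SE 0.039, adjusted p = 7.52e-05) and Fam155a by 0.74 (SE 0.069, adjusted p = 0.0032), each lower in 6 of 6 cKO libraries than in the controls of the same sex. Snhg8 rose by 0.57 (SE 0.054, adjusted p = 0.0032) and was higher in 6 of 6 after subtraction, though its mean was −0.17 on the scale fixed in advance. Atrx fell by 0.67 (SE 0.077, adjusted p = 0.0138). Gm26127 rose by 1.85 (SE 0.239, adjusted p = 0.0332), with 0.429 and 4.34 FPKM in control and cKO females and 0.264 and 1.14 in males.

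Mtfp1 lies on chromosome 11 at 4091480 to 4095445, Fam155a on chromosome 8 at 9205902 to 9771161 and Snhg8 on chromosome 3 at 123507552 to 123508404. These 3 genes passed in each of the 12 fits that left out a library, and were among the 9 called without cKO females 2 and 3, a fit in which the cKO female group is 1 library. The highest adjusted p over the left-out libraries was 0.00102 for Mtfp1 and 0.022 for each of Fam155a and Snhg8. Over all 18 alternatives the adjusted p ran from 0.000103 to 0.884 for Mtfp1, from 0.000576 to 0.769 for Fam155a and from 0.000528 to 1 for Snhg8. Atrx no longer passed without any 1 of the 6 control libraries or cKO male 1 (adjusted p up to 0.0787), nor without cKO females 2 and 3 (0.0514). Gm26127 passed in 1 of the 12 fits, the one without cKO female 1. The count of 5 became 4220 without cKO female 1 and 3 to 6 without any other library.

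**Figure D4:**
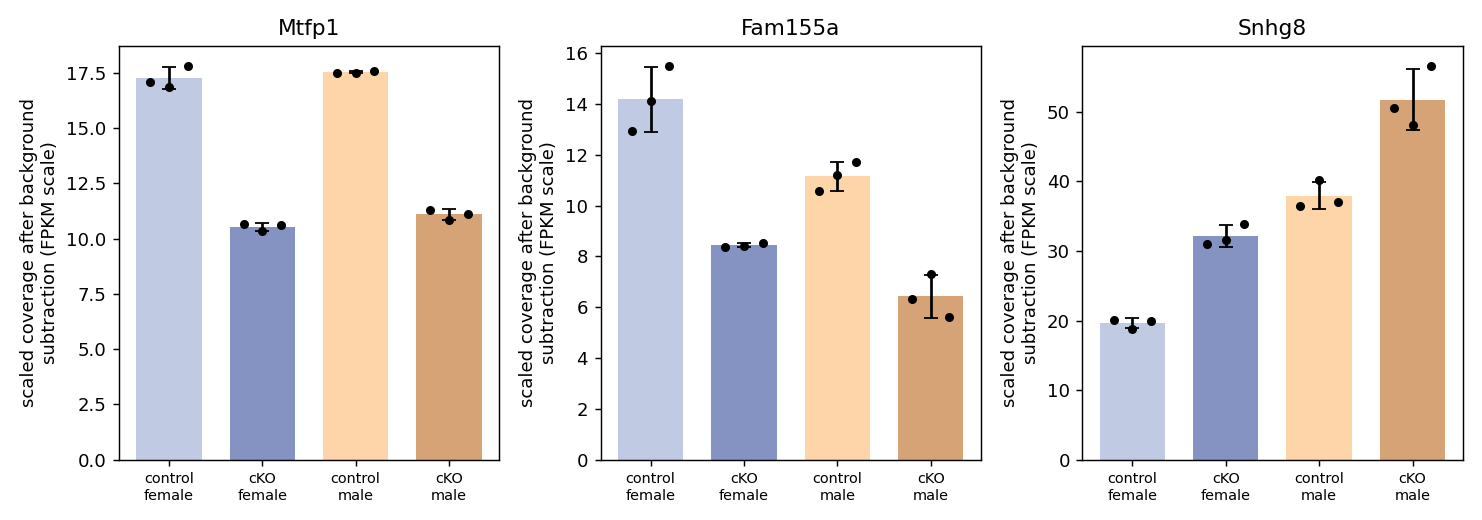
Mtfp1, Fam155a and Snhg8 in the 4 groups as scaled coverage after background subtraction (vertical axis, FPKM scale), with bars for means, error bars for SD and points for libraries (n = 3). The mean of Mtfp1 is 17.2 in control and 10.5 in cKO females, and 17.5 and 11.1 in males, while Snhg8 is higher in the cKO groups, a direction that turns in females on the scale fixed in advance but not in the means of deposited FPKM.

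On the scale fixed in advance, limma called 0 genes for the mean of both sexes, with 16189 at an unadjusted p under 0.05, and voom called 0. Csf2ra had a log2 value of −0.98 (adjusted p = 0.122 over all genes and 0.000131 adjusted over the list alone). Pla2g2f (1.22), Tex13c2 (0.99), Resp18, a gene of neuroendocrine cells (−1.46), Cep112 (−1.06), the arachidonate lipoxygenase Alox8 (−0.92), the growth factor homologue Fgf11 (−0.86), the Polycomb-associated Epop (−0.96) and the T-type calcium channel Cacna1g (−0.87) had adjusted p-values of 0.122 to 0.123. The median of all genes was 0.25 in this comparison.

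The difference between the male and female effects asked whether the response depends on sex, as the title of the series states for miR-137. No gene passed, either on the scale fixed in advance (limma 0, with 1612 at an unadjusted p under 0.05; voom 0; smallest adjusted p 0.703) or after subtraction (limma 0, with 917; smallest adjusted p 0.412). Sez6l, which fell in females, had 12.98 FPKM in control and 13.3 in cKO males, and its difference between sexes was 1.28 (female log2 −1.24, male 0.04, adjusted p = 0.588). Rnf19b differed by −0.73 (0.59 and −0.14, adjusted p = 0.412), Gm37116 by −1.92 (1.85 and −0.08, 0.412), Cttnbp2nl by 2.08 (−2.14 and −0.06, 0.425), Hist3h2ba by 2.03 (−1.94 and 0.10, 0.425), Snora73b by 3.47 (−3.09 and 0.37, 0.425) and Gm26127 by −1.73 (2.72 and 0.99, 0.588). For Mtfp1 the difference was 0.05 (SE 0.077, adjusted p = 0.793), for Fam155a −0.05 (SE 0.138), for Snhg8 −0.26 (SE 0.108) and for Atrx 0.40 (SE 0.153, adjusted p = 0.588). Before subtraction the zinc finger genes Zfp422 (female −1.08, male 1.18) and Zfp664 (−1.11, 1.08), the sulfotransferase Ust (−1.72, 0.65) and the sepiapterin reductase Spr (−1.41, 0.33) had the opposite signs in the sexes and did not pass (adjusted p = 0.703). The median standard error of a difference was 0.281 after subtraction, against 0.199 within a sex. Without cKO female 1 the counts were 3381 and 2957, and without cKO female 3 the count after subtraction was 1.

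Control males were compared with control females as the baseline for sex. Besides the Y-linked genes and Xist (log2 −4.83, adjusted p = 7.89e-06), autosomal genes differed. Among genes higher in males on the scale fixed in advance were Fcgr3, an immunoglobulin receptor of microglia, with 7.81 ± 0.774 FPKM in females and 17.2 ± 2.21 in males (SD, n = 3; log2 1.72, adjusted p = 0.0273), and Trem2, a microglial lipid receptor, with 2.29 and 5.19 (1.62, 0.0273). Among genes higher after subtraction were Ndufs5, which encodes a subunit of mitochondrial complex I, with 58.4 ± 1.83 and 102.6 ± 8.48 FPKM (0.81, 0.000967), and Ndufa4 and Ndufb8 with log2 values of 0.84 and 0.73. Genes lower in males after subtraction included Scamp5 of synaptic vesicles (−0.69, 0.000967), the sodium channel Scn8a (−0.86), the potassium channel Kcnd2 (−0.55) and the cation exchanger Slc24a2 (−0.98). Before subtraction Scamp5 had −0.02 and Kcnd2 turned to 0.06. Each named gene with an adjusted p here lay on 1 side in 3 of 3 libraries.

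Gene lists were also compared between control males and females after subtraction, given as medians relative to all genes. All 13 astrocyte markers lay above (median 0.58; 5 called and 9 adjusted over the list alone; S100b 0.997, Gfap 0.94, Aldoc 0.74, Mlc1 0.58), with adjusted p = 1.5e-06, or adjusted p = 0.0837 with an estimated correlation. So did all 14 microglial markers (median 0.46, adjusted p = 0.000348, or adjusted p = 0.0654 with an estimated correlation), of which 2 were called and 6 adjusted over the list alone. All 16 oligodendrocyte markers lay above (0.37; Mbp 0.998, Mobp 1.24; adjusted p = 0.000702, or adjusted p = 0.525 with an estimated correlation), with 3 called and 6 adjusted over the list alone. All 14 short structural RNAs lay above as well (1.04, adjusted p = 1.9e-05, or adjusted p = 0.36 with an estimated correlation), with 2 called and 3 adjusted over the list alone. The background was lower in each control male than in each control female.

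Of the 9 neuronal lists, 3 passed in control males after subtraction and lay below, as did reported miR-137 targets. Presynaptic release genes had a median of −0.26 (Nsf −0.83, Syt1 −0.67; adjusted p = 0.000348, or adjusted p = 0.36 with an estimated correlation), with 5 of 34 called lower and 15 adjusted over the list alone, and 1 and 2 higher. Postsynaptic glutamate genes had −0.27 (Grin2b −1.10, Gria1 −0.72; adjusted p = 0.000466, or adjusted p = 0.36 with an estimated correlation), with 11 of 35 called lower and 17 adjusted over the list alone. Immediate early genes had −0.34 (adjusted p = 0.00209, or adjusted p = 0.403 with an estimated correlation), with 4 of 21 called and 5 adjusted over the list alone. Reported miR-137 targets had −0.23 (adjusted p = 0.00647, or adjusted p = 0.274 with an estimated correlation), with 6 of 16 called and 7 adjusted over the list alone, among them Nsf, Syt1 and Gria1 of the synaptic lists. GABA receptors (−0.04), interneuron (−0.35), CA1 (−0.22), CA2 and CA3 (−0.20), dentate granule (−0.06) and immature neuron markers (−0.29) did not pass (adjusted p = 0.128 to 0.48). The directions of the 4 lists that passed depended on the processing: on the scale fixed in advance, which differs in subtraction, gene length, filter and scaling, they lay at 0.61, 0.58, 0.47 and 0.56.

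Control males and females differed in 78 genes on the scale fixed in advance (59 higher and 19 lower in males, 64 of them autosomal), around a median of −0.35 for all genes. The split was 212 to 129 on deposited FPKM, 162 to 157 with quantile normalization and 1005 to 801 after subtraction, where 52 of the 78 genes were shared and 1719 of the called genes were autosomal. Leaving out a library gave 9 to 32 genes without any 1 of the control libraries or cKO male 1, 253 without cKO male 3, 2066 without cKO male 2 and 6843 without cKO female 1. After subtraction it gave 547 without control male 3, 743 without control female 1, 767 without control male 2, 918 without control female 3, 1018 without control female 2 and 2791 without cKO female 1.

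Gene lists in the cKO hippocampus were compared after subtraction, with the medians again relative to all genes. In females none of the 27 lists passed (smallest adjusted p 0.121; 0.966 with an estimated correlation), and in males 9 lay lower, none of them with an estimated correlation (smallest adjusted p 0.0967). GABA receptors had a median of −0.14 in males, with 14 of 15 members below (adjusted p = 0.000367, or adjusted p = 0.0967 with an estimated correlation), and −0.05 in females, where their mean had the other sign. Presynaptic release genes lay at −0.12 in males (0.000367, or 0.44) and −0.05 in females, postsynaptic glutamate genes at −0.10 (0.013, or 0.44) and −0.18, and immediate early genes at −0.17 (0.00989, or 0.44) and −0.21. Astrocyte markers lay at −0.20 in males, with 12 of 13 members below (4.07e-05, or 0.147; Aqp4 −0.38), and −0.01 in females. Microglial markers lay at −0.10 (0.0148, or 0.147) and −0.06. Mitochondrially encoded genes lay at −0.70 in males, with 13 of 13 below (2.04e-08, or 0.44), and 0.12 in females. The male libraries overlapped, with summed FPKM of 33924, 64354 and 48872 in controls and 38295, 25977 and 33713 in cKO. Control males 2 and 3 were highest and cKO male 2 was lowest. After subtraction the list was not tested with single libraries left out. The difference between the sexes passed for the mitochondrially encoded list (−0.81, adjusted p = 0.0057, or adjusted p = 0.95 with an estimated correlation) and not for the other 8. In these 9 male lists 0 members were called over all genes, and Aqp4 alone passed when adjusted over the list alone.

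The remaining male lists that lay lower describe tissue beside the hippocampus. Choroid plexus markers had a median of −1.01 in males (adjusted p = 0.000195, or 0.44 with an estimated correlation) and −0.77 in females, and striatal markers −0.32 (0.0196, or 0.44) and −0.49. The choroid plexus gene Ttr, a carrier of thyroid hormone, had 15.4, 5701 and 9.09 FPKM in control females, 23.9, 20.9 and 25.9 in cKO females, 4002, 1570 and 1309 in control males and 2499, 40.9 and 43.0 in cKO males. Blood genes lay at −0.33 in males and 0.12 in females, where mean and median differed in sign, and thalamus and habenula markers at −0.10 and 0.03, the latter with a negative mean.

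Lists tied to ATRX and miR-137 did not pass in either sex after subtraction. Reported ATRX targets, of which 4 were measured, lay at −0.14 in males and 0.46 in females, and ATRX partners and heterochromatin genes at −0.04 in both. Reported miR-137 targets lay at 0.00 in males (adjusted p = 0.722) and 0.01 in females (0.949), with a negative mean in both. The p53 and DNA damage genes lay at −0.01 and −0.24, interferon response genes at 0.07 (negative mean) and 0.17, and imprinted genes at −0.01 (positive mean) and −0.03. Interneuron markers lay at −0.08 in males and 0.03 in females (negative mean), CA1 markers at 0.04 (negative mean) and −0.11, CA2 and CA3 markers at 0.01 and −0.06, dentate granule markers at 0.03 and −0.10 and immature neuron markers at −0.06 and −0.09 (positive mean). Oligodendrocyte markers lay at 0.08 and −0.12, precursors of oligodendrocytes at −0.10 and −0.29, endothelial and mural markers at −0.07 and −0.02, short structural RNAs at 0.06 and −0.63, and the sex chromosome check at 0.01 and 0.00.

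On the scale fixed in advance most lists lay below all genes, as genes of high level did in both sexes. Whether the level of their members accounts for this was not tested. In females 22 of 27 lists lay lower, such as presynaptic release (median −1.42 relative to all genes, adjusted p = 2.15e-15, with 0 of 36 genes called and 25 adjusted over the list alone) and postsynaptic glutamate genes (−1.42, 2.05e-16, with 0 of 35 called and 29 adjusted over the list alone). In males 23 lay lower. None passed with an estimated correlation (smallest adjusted p 0.24 in females and 0.173 in males). Interferon response genes in females had a median of −0.13 and a test in the other direction, and did not pass (adjusted p = 0.781).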

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

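Of the tests below, those on depth, on the gap between genes of low and high level, on the loss of Atrx, on background in the control sex difference and on handling were chosen after the results were seen, as was the background subtraction.

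The median coverage of receptor genes was 1.97 in cKO female 2 and 2.25 in cKO female 3, above every control (at most 0.600), and 0.286 in cKO male 2, above the other males (at most 0.0274) but below control female 3 and cKO female 1 (0.304). Lower sequencing depth ran with the background: the 5 libraries of lowest depth (1.16 to 4.26 Gb) were the 5 of highest background. X-linked silent genes, relative to autosomal ones, had a coverage of 0.69 in cKO male 2 against 1.28 to 1.45 in females. This is a ratio of 0.513 to the female median, close to the ratio of X copies between the sexes. Genomic DNA in the libraries may therefore account for the background. Lower depth alone would not change this ratio, and coverage on the FPKM scale is already relative to mapped bases. The ratio rests on 1 male library, because the other males had too little background, so a part played by depth was not excluded. How such DNA came to differ between groups stays open, and no biological explanation was tested.

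In cKO females, genes with a mean subtracted coverage under 0.1 lay above the controls (median log2 0.52) and genes over 20 lay below (−1.13). The former could pass the filter of 0.5 FPKM in 3 libraries through cKO females 2 and 3 and control female 3 (background 1.97, 2.25 and 0.600). The filter itself thus favours their rise. Among expressed protein-coding genes, the gap between the medians of 5593 genes at 1 to 5 and 1302 over 20 was 0.635, and control male expression with only the background of each female library added gave 0.741, which is consistent with background as a source of this gap. A response of silent genes to loss of Atrx could not be excluded by cKO female 1, whose Atrx was 31.0 FPKM and whose background was 0.508 of the highest control female, because 1 library decides little. For cKO females 2 and 3 loss of Atrx cannot be told apart from background, since both hold the same libraries. Elsewhere background did not run with Atrx alone. Control female 3, with 63.6 FPKM of Atrx, had a background of 0.600, above the 0.304 of cKO female 1. cKO males 1 and 3, with 34.2 and 36.5 FPKM, had 0.0205 and 0.0178, within the control males (0.00664 to 0.0274). cKO male 2 lay above them at 0.286.

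Autosomal genes differed between control males and females. Of 783 autosomal genes called at an FPKM of at least 5, 754 were higher in males. After subtraction 426 of the 783 were also called in the same direction and 0 in the opposite one. This leaves open the other genes of the 1719 called after subtraction. It cannot decide on background as the source, because 1 level per library was subtracted while background varied between genes. A trend with level remained after subtraction, with a median log2 difference of −0.111 for genes at 1 to 5 and 0.138 for genes over 20. Separate handling of female and male libraries cannot be told apart from sex: 8 of 14 short structural RNAs separated all 6 female from all 6 male libraries, against 18.4% of all genes and 0.22% by chance. A trend with gene length was present, with a gap of 0.316 between the shortest and longest protein-coding genes and 0.206 in all autosomal genes, and the calls ran with length (311 higher and 40 lower in males among the 2112 shortest, 49 and 276 among the 2112 longest), so length and sex cannot be told apart. Sex itself stays open, untested apart from handling.

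Gm10800, a gene at the edge of a satellite repeat on chromosome 2 (98666547 to 98667301), had 123372 FPKM in cKO female 2, 136905 in cKO female 3 and 61102 in cKO male 2, against 34538 in cKO female 1, 8131 and 12583 in cKO males 1 and 3, 13193 to 40662 in control females and 6220 to 9992 in control males, so it did not follow genotype alone. Gm10800 ran largely with the background of receptor genes, which was 1.97 and 2.25 in cKO females 2 and 3. Control female 3 (background 0.600) lay above cKO female 1 (0.304), though cKO male 2 (0.286) lay above both. The cause was not tested. A difference between the sexes in the cKO effect after subtraction was found for mitochondrially encoded genes (−0.811) and for short structural RNAs (0.766), neither of which passed with an estimated correlation.

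Other splits of the libraries were fitted beside each count of genes. Where the real split called 0 genes, every split called at least as many, so the number of splits (10 of 10 in cKO females and in cKO males, 100 of 100 for the mean and for the difference between sexes) decides nothing. The highest other split called 23328 genes in females, 14 in males, 21347 for the mean and 20848 for the difference, which points to a structure of the samples other than genotype. For control males against females 1 of 10 splits, the real one, called 78 genes and the highest other 1, too few splits for a share under 0.05. After subtraction, 2 of 10 splits called as many genes as the real one in females (11, highest other 940) and 5 of 10 in males (1, highest other 9), too few splits for a share under 0.05. For the mean of both sexes after subtraction, 2 of 100 splits called as many as the real 5 genes, the real one and another with 6. This share is under 0.05, but it does not exclude chance. Atrx, the deleted gene, is among the 5 and favours the real split, and the subtraction was chosen after seeing the data. Before subtraction the real split called 0 genes.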

How the results depend on the processing

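The background subtraction, the fits without cKO females 2 and 3, the scaling over expressed genes and the background covariate were chosen after seeing the data. Counts of genes past the threshold are given in the order cKO females, cKO males, difference between sexes, mean of both sexes and control sex difference, where they moved from 0, 0, 0, 0 and 78. FPKM as deposited gave 10452 in females, 5 for the mean and 341 for the control sexes. Quantile normalization gave 15, 1 and 319 for the same comparisons. A pseudocount of 0.1 gave 2931 for the control sexes, no filter 10, and no robust option 12. A filter at an FPKM of 5 gave 1 in females and 832 for the control sexes, with fewer genes tested. Library quality weights gave 35984, 2352, 32309, 34406 and 32501, with a weight of 318 on control female 1 and a weight estimate that stopped before convergence. voom on estimated reads gave 1 in females and 5115 for the control sexes, and the libraries of a comparison alone gave 3 and 7362. Transcripts gave 58, 21, 20, 26 and 49. With a replicate block by pairs within a sex, 3 genes were called in females, and with a replicate block by number 47 for the control sexes. The subtraction gave 11, 1, 0, 5 and 1806, and 16, 1, 0, 9 and 3394 without cKO females 2 and 3, whose removal alone gave 4326 for the control sexes. Scaling over expressed protein-coding genes gave 18053 in females, 4 for the mean and 785 for the control sexes, and 2 and 1699 for the mean and the control sexes with a filter at an FPKM of 5. The background covariate gave 1, 2, 1, 1 and 9. Autosomal genes differing between control sexes numbered 64, and ran from 3 with the covariate to 30843 with quality weights. The cause was not tested beyond the background, the number of genes and the libraries used.

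Leaving out 1 library gave 0 to 24391 genes in females (24391 without cKO female 1, 8886 without control female 3, 101 without cKO male 2), 0 to 1 in males, 0 to 3381 for the difference between sexes, 0 to 23000 for the mean (3381 and 23000 without cKO female 1), and 9 to 6843 for the control sexes. Autosomal genes among these ran from 2 to 6266. After subtraction the ranges were 1 to 5556 in females, 1 to 2 in males, 3 to 4220 for the mean and 547 to 2791 for the control sexes.

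Directions turned as follows, and the cause was not tested. On the scale fixed in advance, without subtraction, Snhg8 was −0.528 in females and −0.173 for the mean, and Rnf19b was −0.724 in females, with −0.034 on deposited FPKM, −0.08 with quantile normalization and −0.094 with the covariate. With quantile normalization, list medians turned in females for miR-137 targets (0.008) and mitochondrially encoded genes (0.114), in males for miR-137 targets (0.025), imprinted genes (0.02) and oligodendrocyte markers (0.094), in the difference between sexes for astrocyte markers (−0.075), and for the mean for ATRX partners (0.009) and miR-137 targets (0.009). For the control sexes they turned for ATRX partners (−0.049), miR-137 targets (−0.398), presynaptic (−0.422) and postsynaptic genes (−0.396), GABA receptors (−0.294), interneuron markers (−0.283), imprinted genes (−0.252), CA2 and CA3 (−0.193), dentate granule (−0.222), endothelial (−0.029) and thalamus markers (−0.079), mitochondrially encoded genes (−0.628) and the sex chromosome check (−0.481). On leaving out 1 library, choroid plexus genes in females ran from −1.495 to 0.088 (without control female 2), blood genes in females from −1.868 to 0.066 (without cKO female 2) and oligodendrocyte markers in males from −0.545 to 0.223 (without cKO male 2). Of 105 named gene results, 80 kept their direction and side of the threshold on deposited FPKM, 22 became stronger and 3 weaker. All 107 list calls were lost with an estimated correlation. Depth of 1.16 Gb in cKO female 2 limits values of low genes there.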

Other observations

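Genes whose libraries did not overlap between cKO and control moved the same way in both sexes more often than independence of the sexes gives. After subtraction, 2585 of 14770 genes separated in females and 1792 in males, against 1477 by chance. In both sexes 147 were lower and 221 higher in all 3 cKO libraries, against 56.1 and 104 if the sexes were independent at their measured shares, and 22 and 19 went opposite ways, against 84.7 and 68.9. Among 5373 protein-coding genes with a mean of at least 5 the numbers were 77, 66, 6 and 6 against 30, 23.9, 24.1 and 29.8, with 841 separating in females and 689 in males. Genes that move together are not independent, so no p was attached. Mean background was higher in cKO than in control libraries of both sexes (1.51 against 0.289 in females and 0.108 against 0.0156 in males). Its part in this agreement was not tested. After subtraction the shortest autosomal genes also lay above the longest in cKO, by 0.265 in females and 0.148 in males. In protein-coding genes these gaps were −0.034 and 0.016. Besides Mtfp1, Fam155a and Atrx, Wfs1, a protein of the endoplasmic reticulum and marker of CA1 neurons, was lower in all 3 cKO libraries of each sex after subtraction. Its log2 change was −0.55 in females and −0.41 in males, which passed when adjusted over the list alone (adjusted p = 0.00305 and 0.0262) but not over all genes (0.118 and 1), and its female libraries overlapped on deposited FPKM. Tdo2, a tryptophan-degrading enzyme and marker of dentate granule cells, separated in males after subtraction, but its female libraries overlapped. On deposited FPKM it was higher in all cKO libraries of each sex. Its log2 change was 0.68 in females and 0.997 in males, and it passed in males when adjusted over the list alone (adjusted p = 0.0204).

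A few interferon genes were higher in cKO females after subtraction, though their list did not pass. Ifit3, an antiviral protein, had 4.56 ± 0.836 FPKM in controls and 8.63 ± 1.53 in cKO females (log2 1.16, adjusted p = 0.118 over all genes and 0.00449 adjusted over the list alone). Gbp2 (log2 0.69), Gbp3 (0.57) and Ifit3b (0.59) also passed on the list alone (adjusted p = 0.0367 each), so that 4 of 10 measured members were higher and 1 lower on that basis. The background was highest in the same group. At the level of single transcripts, a difference between the male and female effects was called for 20 of 80411, 14 higher and 6 lower in males. One was a transcript of Gria2, a subunit of the AMPA glutamate receptor, with log2 changes of −6.18 in females and −0.27 in males, and others belonged to Usf1, Akt2, Tnpo1 and Rrp1. These were called without subtraction, and transcript values rest on how the submitters' software shared reads among transcripts. Across 14770 genes the female and male effects correlated with r = 0.411 after subtraction, and across 43399 genes with r = 0.625 before it, with genes not independent replicates. Background was raised in cKO females 2 and 3 and in cKO male 2, so this agreement is not independent of it.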
